A study of Mus musculus with 8 samples.

How the data were processed

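Gene expression was measured with Illumina MouseRef-8 v2 bead arrays in Gr1+ cells sorted with magnetic beads from pooled spleens of female C57BL/6 mice of 6 to 8 weeks. The extraction text of the labels gives pools of 10 to 15 spleens and the design text gives 30 to 40. HY209 or PBS was injected 30 min after LPS or PBS, spleens were taken at 48 h, more than 95% of the Gr1+ cells were CD11b+, and 550 ng of RNA was used per array. The groups were taken from the sample titles: PBS (2 arrays, numbered 1 and 3), LPS (3 arrays) and LPS followed by HY209 (3 arrays, LPS_HY209 in array names). The description of PBS 3 gives it the number 2, and the number of its title was used.

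The deposited values are intensity on a linear scale, 1 column for each of the 8 arrays, quantile normalized between the arrays by the authors and not background-subtracted. The quantiles of the 8 columns differ by at most 0.0539%, and the lowest value is 108.9. The labels name GenomeStudio 2011.1 and R 2.15.0 and give no filter. A second table with 8 signal columns and their detection p-values (16 columns) is not used here, because its column names match no sample title. The depth of an array is its signal over background. The mode of the intensities was 148 with a spread of 0.11 on the log2 scale, which puts the upper 5% bound of background at 168. On each array 13078 of 25697 probes (50.9%) lay above it, the same number because of the quantile normalization.

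From these values, background was corrected with normexp and an offset of 50, followed by quantile normalization and log2 transformation in limma 3.58.1 (R 4.3.3). Probes above the background threshold on at least 2 arrays were kept (14823). The plan made before the data were examined filtered on detection p-values, and this threshold took its place after the table was seen and before any gene was tested. Of all probes, 23978 carried 1 gene symbol, 0 carried several and 1719 carried none. Symbols were checked by Entrez identifier against the RefSeq names of GRCm38.p6 for 23962 probes, and 0 changed. Genomic positions are not used here. For each gene the probe with the highest mean was used, which left 10273 genes for testing, and 2614 of 16593 genes on the arrays had at least 2 probes. No named gene but Ahnak, which the results leave out, had another probe past the test in the opposite direction.

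One linear model with a mean per group was fitted to all 8 arrays with limma (lmFit and eBayes, two-sided, 5 residual degrees of freedom plus 6.60 from the prior), with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. The median standard error of a log2 change was 0.11 for LPS against PBS, 0.10 for HY209 against LPS and 0.11 for HY209 against PBS. On simulated data with 200 changed genes, a log2 change of 1 was recovered for 94.0%, 98.5% and 98.5% of the genes in these comparisons, and a change of 0.5 for 55.2%, 70.1% and 53.7%. Of 10043 unchanged genes, 0.0697%, 0.0996% and 0.0797% were called. Far more genes passed the test in the data (5709, 979 and 4873). That loosens the cut on the unadjusted p, so recovery there can differ. All folds and log2 changes are on the background-corrected scale, while intensities are printed as deposited. Where no array of a group exceeded the threshold, the fold is given as a lower bound on the corrected scale, computed against the threshold there (a log2 value of 6.65), and it can exceed the ratio of the printed intensities.

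Gene lists (26, of which 13 are for cell types and 13 for pathways, with 1030 members listed) were fixed before the data were examined and tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Named genes follow a rule fixed at the same time. It takes the 10 largest rises and falls past the test whose arrays do not overlap, up to 4 members past the test per list, and 10 genes in every case (Itgam, Ly6g, Ly6c1, Gpbar1, Arg1, Nos2, Il10, S100a8, S100a9 and Cd274). Members of a list are also named where 5 or fewer passed the test in a direction. Those outside the rule were chosen after their values were seen, as were Egr1 against PBS and the genes named in the closing section. For shared control arrays, the covariance of the changes was set beside 500 simulations of unchanged groups. The replicate numbers were checked for pairing. The residuals of 7 same-numbered pairs of arrays correlated from -0.19 to 0.29 across genes, and 2 of them exceeded 0.1. The pairs of LPS with HY209 arrays had 0.05, 0.29 and 0.27. The numbers were not treated as pairs in the main fit, but pairing is not ruled out, and a block for the number was run as an alternative. With PBS 3 numbered 2, its pairs correlated by 0.06 and 0.25, and the pairs of replicate 1 stay as low as 0.04.

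The alternatives were no background correction, the deposited values on a log2 scale, scaling to the 75th percentile, no filter or a stricter filter on dim probes (above 178 on every array of at least 1 group), every probe tested, a block for the replicate number, only the groups compared in the fit, trend and robust moderation, array weights, leaving out each array in turn and the estimated correlation. An offset of 16 and centring on the median of the tested genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.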

Results

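Gene expression was measured in Gr1+ cells sorted with magnetic beads from the spleens of female C57BL/6 mice. Gr1 is a surface marker carried mostly by granulocytes and some monocytes. The PBS arrays also held strong signal for genes of other cell types, as the closing section gives. Mice received lipopolysaccharide (LPS, a bacterial cell wall component that sets off a sepsis-like inflammation) or PBS into the peritoneum. They then received HY209 (sodium taurodeoxycholate, a bile salt and a known agonist of the bile acid receptor GPCR19, encoded by Gpbar1) or PBS intravenously. Spleens were collected at 48 h and pooled. The 8 arrays fall into 3 groups: PBS with 2 arrays (numbered 1 and 3), LPS with 3 arrays and LPS followed by HY209 with 3 arrays. No group received HY209 without LPS. The lowest intensity was 108.9 and the median was 169.7 on every array, and 13078 of the 25697 probes (50.9%) lay above background on each. The number of arrays per group limits the precision of every value. In all that follows, ± after a log2 change is the standard error from the fit, ± after an intensity is the SD over the arrays of a group, and n is 2 for PBS and 3 for each of the other groups. Intensities are the deposited values, while folds, bounds and log2 changes come after background correction, so a fold is not the ratio of the intensities beside it. The p-values measure the spread between arrays. The labels give pools of 10 to 15 or of 30 to 40 spleens, so whether each array had its own pool of mice cannot be told. If arrays of a group shared a pool, the p-values would leave out the spread between mice.

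The LPS arrays stood far from the PBS arrays, and the arrays with HY209 stood near those with LPS alone. Over the 10273 genes tested, the first principal component held 83.9% of the variance and parted PBS from both LPS groups, and the second held 6.43% and parted HY209 from LPS alone. The SD of the log2 differences between a pair of arrays was 0.16 within PBS, 0.18 to 0.21 within LPS and 0.19 to 0.23 within the HY209 group. It was 0.25 to 0.31 between LPS and HY209 arrays, 0.79 to 0.81 between LPS and PBS arrays, and 0.69 to 0.75 between HY209 and PBS arrays.

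The first comparison, LPS against PBS, gives the effect of the endotoxin on the Gr1+ fraction of the spleen. The largest rises after LPS included genes of inflammatory chemokines, acute phase proteins and immunoregulatory products. Cxcl2, a chemokine that attracts neutrophils (probe ILMN_2811154), rose 77.2-fold, from an intensity of 206 ± 1.41 to 10703 ± 98.0 (log2 change 6.27 ± 0.20, adjusted p = 3.3e-10). Il10, an anti-inflammatory cytokine (probe ILMN_1238505), rose 31.4-fold from 172 ± 3.92 to 3354 ± 81.9 (4.97 ± 0.09, adjusted p = 9.9e-12). Arg1, the arginine-degrading enzyme of suppressive myeloid cells (probe ILMN_2952275), was below the background threshold on both PBS arrays and at least 19.6-fold higher after LPS on the corrected scale, at an intensity of 2038 ± 24.5. Many transcripts of macrophages, B cells, T cells and red cell precursors were lower, among them the mannose receptor Mrc1 (probe ILMN_1239430), which fell 13.1-fold from 19088 ± 1195 to 1515 ± 107 (-3.72 ± 0.10, adjusted p = 7.6e-11).

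The 10 largest rises included Saa3, an acute phase protein (6.25 ± 0.13), Prok2, a myeloid secreted peptide (5.84 ± 0.19), Orm1, another acute phase protein (5.42 ± 0.09), and Ccl3, a chemokine of macrophages and neutrophils (5.25 ± 0.11). The others were Gpr84, a receptor for medium-chain fatty acids (5.02 ± 0.11), the uridine phosphorylase Upp1 (4.96 ± 0.08) and Ikbke, a kinase of the interferon and NF-kB pathways (4.87 ± 0.09), beside Cxcl2, Il10 and Arg1. Among the 10 largest falls, the prostaglandin-degrading enzyme Hpgd changed by -4.88 ± 0.10, transferrin (Trf) by -4.41 ± 0.14, Crip2 by -4.13 ± 0.20, the organic anion transporter Slco2b1 by -4.07 ± 0.12 and the integrin Itgad by -4.06 ± 0.10. The eosinophil chemokine receptor Ccr3 was at least 13.7-fold lower on the corrected scale, the complement component C6 changed by -4.01 ± 0.11, Vstm4 by -3.99 ± 0.10, the lectin Clec4g by -3.88 ± 0.17 and the growth factor Igf1 by -3.84 ± 0.10. These 20 genes were picked among those whose arrays do not overlap, so every LPS array lay beyond both PBS arrays by that choice.

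**Figure D1:**
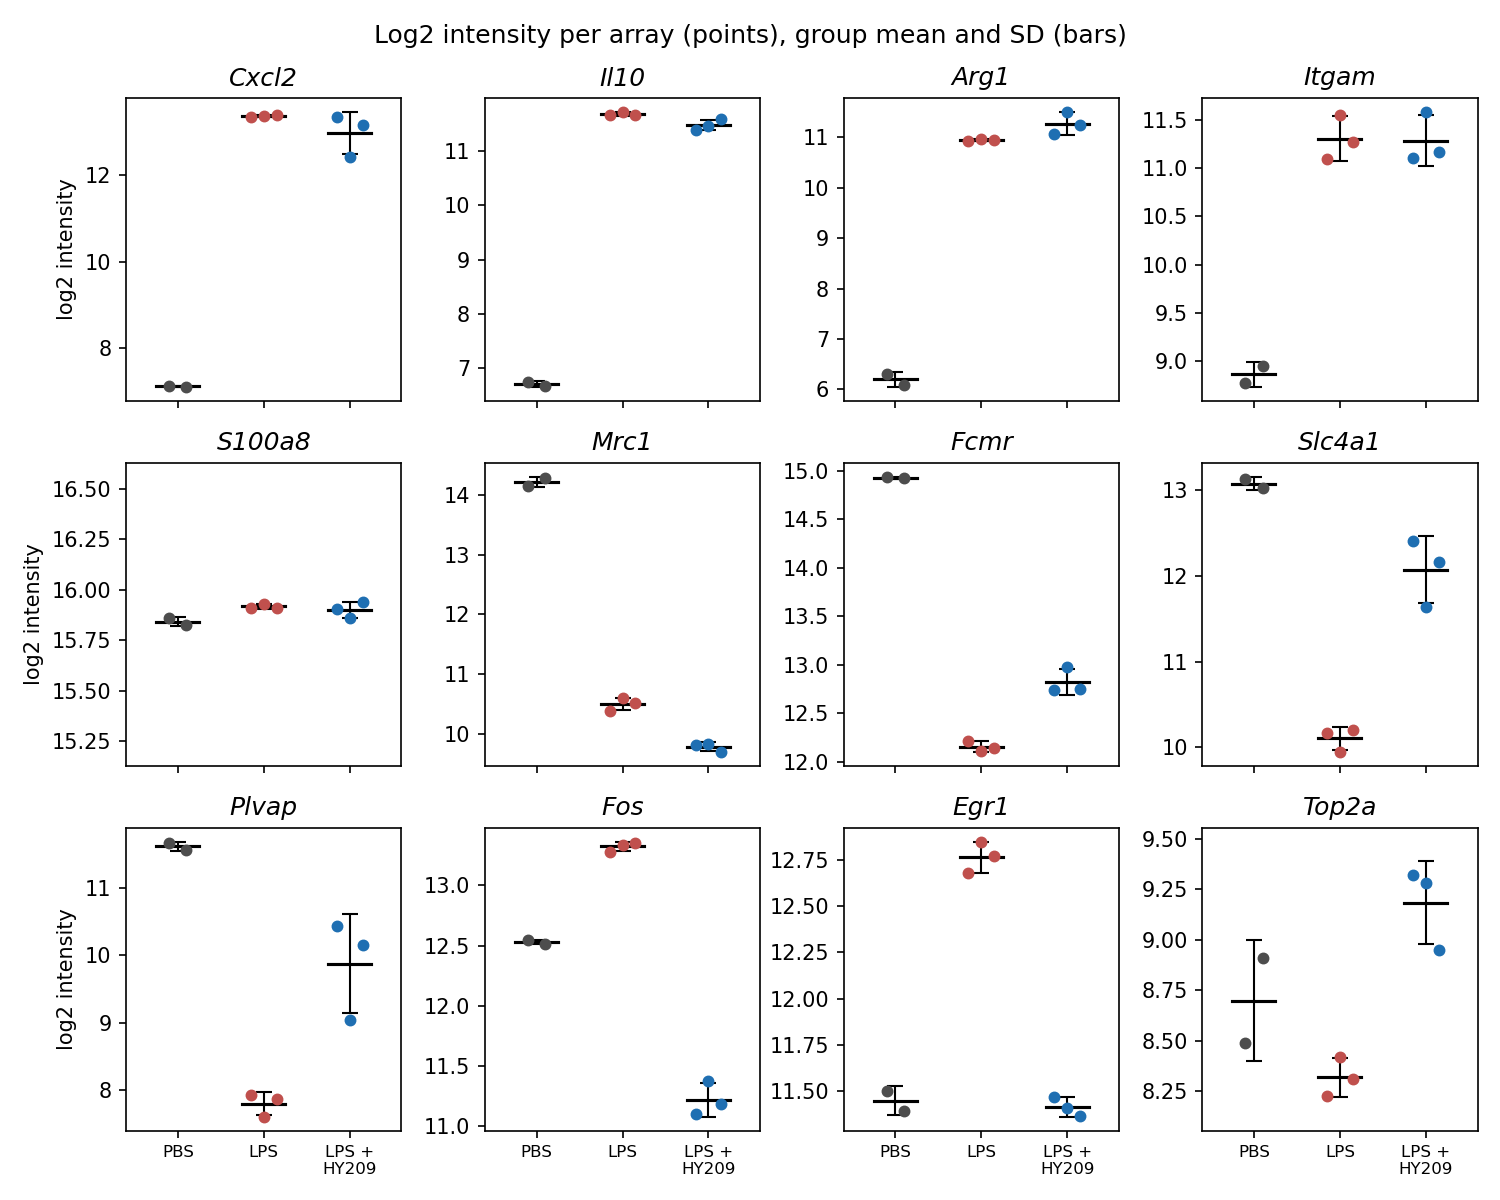
Log2 intensity after background correction of 12 named genes on each array (points, y axis with its own range in each panel and at least 1.5 log2 units high), with the group mean and SD as black bars for PBS (2 arrays), LPS (3) and LPS followed by HY209 (3). Cxcl2, Il10, Arg1 and Itgam were high in both LPS groups. As deposited, before that correction, the mean intensity of Fos fell from 10309 after LPS to 2464 with HY209 and that of Plvap rose from 292 to 1086.

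Of 26 lists of genes for cell types and pathways, fixed before the data were examined, 14 passed the list test with a preset correlation between genes and 6 with an estimated one. Where no other count is given, the count adjusted over the list alone was the same. A second median, at the bounds, sets genes below background in a whole group at the bound of their change. Of 55 tested interferon response genes, 48 rose and 1 fell (50 and 1 adjusted over the list alone), with a median log2 change of 1.24 (adjusted p = 1.1e-16, and adjusted p = 0.0031 with an estimated correlation). The chemokine Cxcl9 changed by 3.23 ± 0.09, the ubiquitin-like Isg15 by 2.67 ± 0.10 and the guanylate-binding protein Gbp2 by 2.27 ± 0.09, and the member that fell was Ifi27. Among 47 inflammatory cytokine and NF-kB target genes, 38 rose and 3 fell, with a median log2 change of 1.40, or 1.16 at the bounds (adjusted p = 1.3e-13, and adjusted p = 0.0092 with an estimated correlation). Tnf changed by 3.72 ± 0.09 beside Cxcl2, Saa3 and Ccl3, and the members that fell were Il18, Cd40 and Ccl9. In the list for suppressor myeloid cells (37 tested, 17 of the listed genes also in another list), 27 rose and 5 fell, with a median log2 change of 0.94 (adjusted p = 7.8e-08, and adjusted p = 0.0092 with an estimated correlation). Its falls were Mrc1, Tgfb1, Ccl6, Nt5e and Il10ra.

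Of the 3 neutrophil lists, 2 rose, for maturity and activation and for secondary and tertiary granules. Of 33 genes of neutrophil maturity and activation, 24 rose and 3 fell, with a median log2 change of 1.05 (adjusted p = 3.7e-09, and adjusted p = 0.010 with an estimated correlation). Examples were the stefins Stfa2 (4.49 ± 0.13) and Stfa1 (2.83 ± 0.14), the decoy receptor Il1r2 (3.02 ± 0.10) and the lectin Clec4e (2.74 ± 0.10), and the falls were Ccl6, Csf3r and Gadd45a. Of 29 secondary and tertiary granule genes, 21 rose and 2 fell, with a median log2 change of 0.93, or 0.64 at the bounds (adjusted p = 5.1e-06, and adjusted p = 0.013 with an estimated correlation). The falls were Lyz2 and Camp, and Olfm4 (2.18 ± 0.26), the leukotriene receptor Ltb4r1 (1.87 ± 0.10) and Chil1 (1.90 ± 0.09) rose, the last to near the top of the intensity scale, where a change can be compressed. Itgam, which encodes the CD11b chain carried by the sorted cells, rose 5.40-fold from 535 ± 42.0 to 2612 ± 415 (2.43 ± 0.16), and Cd274, which encodes PD-L1, rose 4.44-fold from 4013 ± 132 to 17595 ± 587 (adjusted p = 2.8e-09). S100a8 stood at 58814 ± 953 in PBS and 62004 ± 501 after LPS (0.08 ± 0.08, adjusted p = 0.47), and S100a9 at 36883 ± 2991 and 42780.4 ± 3428 (0.21 ± 0.11, adjusted p = 0.13), both also near the top of the scale. Ly6c1 changed by 0.67 ± 0.09, and Nos2 by 0.72 ± 0.19 (adjusted p = 0.0066, and adjusted p = 0.13 without PBS 3). In the same arrays the lists for B cells, T and NK cells, macrophages and erythroid cells fell with the preset correlation, and of these the B cell list alone also with an estimated one.

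Among 25 B cell genes, 2 rose and 21 fell, with a median log2 change of -1.60 (adjusted p = 1.5e-08, and adjusted p = 0.0092 with an estimated correlation). The IgM receptor Fcmr fell 6.84-fold from 31279 ± 207 to 4633 ± 175 (-2.77 ± 0.10), Fcer2a, which encodes CD23, changed by -3.78 ± 0.17, and Pou2f2 and Cd37 were the members that rose. Of 35 T and NK cell genes, 0 rose and 30 fell, with a median log2 change of -1.16 (adjusted p = 3.5e-10, and adjusted p = 0.16 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, changed by -2.11 ± 0.12, Thy1 by -2.11 ± 0.17 and the transcription factor Ets1 by -2.33 ± 0.12. In 25 MHC class II and dendritic cell genes, 3 rose and 21 fell, with a median log2 change of -1.70 (adjusted p = 7.8e-08, and adjusted p = 0.13 with an estimated correlation). H2-Ob changed by -3.33 ± 0.13, the class II master regulator Ciita by -2.58 ± 0.12 and the costimulatory Cd86 by -2.55 ± 0.10, while Irf7, Cd80 and Bst2 rose. Of 22 macrophage genes, 4 rose and 16 fell, with a median log2 change of -1.21 (adjusted p = 1.5e-05, and adjusted p = 0.14 with an estimated correlation). Axl fell 9.31-fold from 46528 ± 411 to 5063 ± 167 (-3.22 ± 0.09) and Apoe changed by -2.64 ± 0.10, while Marco, Ctsd, Ctsz and Sirpa rose. Among 33 erythroid genes, 4 rose and 24 fell, with a median log2 change of -0.99, or -0.86 at the bounds (adjusted p = 2.8e-05, and adjusted p = 0.20 with an estimated correlation). Alas2, the first enzyme of heme synthesis, changed by -3.24 ± 0.17, the red cell anion exchanger Slc4a1 by -2.97 ± 0.18, and Isg20, Ube2l6, Nfe2 and Mt2 rose. Of 54 ribosomal protein genes, 2 rose and 43 fell (2 and 44 adjusted over the list alone), with a median log2 change of -0.59 (adjusted p = 1.4e-08, and adjusted p = 0.10 with an estimated correlation). Rpl27a changed by -1.99 ± 0.12 and Rpl22 by -1.94 ± 0.11, and Rpl24 and Rpl7a rose.

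Smaller rises were called for apoptosis regulators, adhesion receptors and immediate early genes with the preset correlation. Of 31 apoptosis regulators, 15 rose and 6 fell (16 and 6 adjusted over the list alone), with a median log2 change of 0.32, or 0.23 at the bounds (adjusted p = 0.025, and adjusted p = 0.12 with an estimated correlation). The death receptor Fas changed by 1.94 ± 0.09 and the inflammatory caspase Casp4 by 1.95 ± 0.09. Among 23 adhesion and migration receptors, 12 rose and 5 fell, with a median log2 change of 0.36 (adjusted p = 0.030, and adjusted p = 0.25 with an estimated correlation). Pecam1, Cd44, Icam2, Ccr7 and Itga1 fell. In 22 handling stress and immediate early genes, 14 rose and 6 fell, with a median log2 change of 0.44 (adjusted p = 0.030, and adjusted p = 0.28 with an estimated correlation). Gadd45b changed by 2.73 ± 0.12, Ier3 by 2.69 ± 0.09, Jun by 2.49 ± 0.10 and the heat shock protein Hsph1 by -2.24 ± 0.21. The remaining lists did not pass the list test. Primary granule genes had 5 higher and 4 lower of 12 (median 0.22, adjusted p = 0.61), with Srgn, Prtn3, Elane, Mpo and Ms4a3 higher and Igfbp4, Nkg7, Ctsc and Calr lower. For that list the mean was -0.07 while the median and the test pointed up. Monocyte genes had 5 higher and 9 lower of 19, 6 and 9 adjusted over the list alone (median -0.25, adjusted p = 0.39), with Cd14, the LPS co-receptor, higher (2.66 ± 0.09) beside Ms4a6d, Clec4a1, Ly6c1 and Lgals3, and the fractalkine receptor Cx3cr1 lower (-3.26 ± 0.14). Plasma cell genes had 1 higher and 5 lower of 14 (median -0.14, adjusted p = 0.28), with Xbp1 higher and Mzb1, Irf4, Tnfrsf17, Fkbp11 and Slamf7 lower. Megakaryocyte and platelet genes had 4 higher and 10 lower of 19 (median -0.33, or -0.13 at the bounds, adjusted p = 0.24), with P2rx1, Selp, Thbs1 and Plek higher. Eosinophil, basophil and mast cell genes had 4 higher and 5 lower of 15, 4 and 6 adjusted over the list alone (median -0.13, or -0.07 at the bounds, adjusted p = 0.98), with Ear6, Cd63, F2rl3 and Hdc higher and Ccr3, Prg3, Gata2, Il4 and Prss34 lower.

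Stem and progenitor genes had 6 higher and 5 lower of 19 (median 0.02, or 0.01 at the bounds, adjusted p = 0.74), with Egfl7, Tal1, Lmo2, Gata2 and Meis1 lower and a mean of -0.03 against the positive median. Cell cycle genes had 6 higher and 12 lower of 40, 6 and 10 adjusted over the list alone (median -0.04, adjusted p = 0.74), with Mcm10 at 0.79 ± 0.11 and Kif23 at -1.08 ± 0.10. Oxidative burst and antioxidant genes had 13 higher and 8 lower of 31 (median 0.26, adjusted p = 0.28), with the superoxide dismutase Sod2 at 2.35 ± 0.09 and catalase (Cat) at -2.05 ± 0.12. The bile acid and cAMP list had 8 higher and 9 lower of 24 (median 0.11, adjusted p = 0.29), with Per1 at 2.19 ± 0.11 and the vitamin D receptor Vdr at 2.08 ± 0.14. Unfolded protein response genes had 12 higher and 9 lower of 28, 12 and 11 adjusted over the list alone (median 0.16, or 0.08 at the bounds, adjusted p = 0.74), with a mean of -0.05, the asparagine synthetase Asns at 1.43 ± 0.10 and Chac1 at -1.81 ± 0.11. Glycolysis genes had 8 higher and 4 lower of 23 (median 0.08, adjusted p = 0.31), with Pfkm, Aldoc, Pdk1 and Hk2 lower. Oxidative phosphorylation genes had 10 higher and 14 lower of 62 (median -0.08, adjusted p = 0.64).

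With limma, 2629 genes were higher and 3080 lower after LPS at an adjusted p under 0.05, of which 649 and 835 changed at least 2-fold. The arrays of both groups did not overlap for 71.0% of the genes tested, against 20% by chance for 3 arrays against 2. Among the genes named here, Camp, Csf3r, Gadd45a, Cd37, Xbp1, Fkbp11, Meis1, Il10ra, Prss34, Ctsz, Slamf7, Calr, Ms4a3, Rpl7a, Sirpa, Itga1 and Nos2 lost their call without at least 1 single array, with an adjusted p of up to 0.24.

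The second comparison, LPS followed by HY209 against LPS alone, gives the effect of the bile salt in mice with endotoxin inflammation. The change was much smaller than that after LPS. The largest rises with HY209 included genes known from blood vessel endothelium and red cell precursors. Plvap, a protein of endothelial fenestrae (probe ILMN_2984110), rose 4.22-fold from 292 ± 26.0 to 1086 ± 442 (log2 change 2.08 ± 0.27, adjusted p = 0.0011), with 3218 ± 157 in PBS. The immediate early transcription factor Fos (probe ILMN_2750515) fell 4.29-fold from 10309 ± 283 to 2464 ± 239 (-2.10 ± 0.09, adjusted p = 3.7e-07), below its PBS level of 5981 ± 81.7. Mrc1 fell further (-0.72 ± 0.09, adjusted p = 0.00080).

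Of the 10 largest rises, 3 belong to the erythroid list: Slc4a1 (1.97 ± 0.16, from 1171 ± 102 to 4468 ± 1131, with 8716 ± 479 in PBS), the water channel Aqp1 (1.77 ± 0.13), also known from endothelium, and Trim10 (1.34 ± 0.10). Beside Plvap, the others were Igfbp7 (1.84 ± 0.22), Ccn2, a matrix-associated growth factor (1.82 ± 0.11), Sparc (1.67 ± 0.18), the basement membrane collagen Col4a1 (1.48 ± 0.10), Ramp2 (1.43 ± 0.15) and the endothelial receptor Robo4 (1.37 ± 0.14). After Fos, the largest falls were the immediate early genes Ier2 (-1.92 ± 0.10, from 738 ± 49.7 to 245 ± 19.6) and Egr1 (-1.35 ± 0.08, from 7029 ± 405 to 2798 ± 100.3) and the endocytic adaptor Sgip1 (-1.45 ± 0.12). They were followed by the collagenase Mmp13 (-1.13 ± 0.11), Slc16a9 (-0.98 ± 0.08), C6 (-0.97 ± 0.10), Itgad (-0.97 ± 0.09), Rab15 (-0.97 ± 0.10) and Rasl11b (-0.88 ± 0.07). These 20 genes were picked among those whose arrays do not overlap, so all 3 HY209 arrays lay beyond all 3 LPS arrays by that choice.

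With the preset correlation 10 lists rose with HY209, and of these the B cell list alone also with an estimated one. Of 40 cell cycle genes, 28 rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 change of 0.45 (adjusted p = 5.3e-21, and adjusted p = 0.062 with an estimated correlation). Top2a, a topoisomerase of dividing cells, changed by 0.87 ± 0.13, Uhrf1 by 0.80 ± 0.14, Prc1 by 0.75 ± 0.11 and Cdca3 by 0.73 ± 0.13. Of 25 B cell genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 change of 0.60 (adjusted p = 1.3e-12, and adjusted p = 0.011 with an estimated correlation). Ccr6 changed by 0.94 ± 0.10, Pou2af1 by 0.91 ± 0.11, Cxcr5 by 0.83 ± 0.08 and Tnfrsf13c, the BAFF receptor gene, by 0.79 ± 0.09. Among 33 erythroid genes, 16 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 change of 0.29, or 0.23 at the bounds (adjusted p = 2.2e-10, and adjusted p = 0.067 with an estimated correlation). Alas2 changed by 0.86 ± 0.16, and the member that fell was Isg20. Of 19 megakaryocyte and platelet genes, 10 rose and 1 fell, with a median log2 change of 0.34 (adjusted p = 8.8e-06, and adjusted p = 0.062 with an estimated correlation). Alox12 changed by 0.98 ± 0.11, Treml1 by 0.97 ± 0.09, the platelet chemokine Ppbp by 0.90 ± 0.10 and Itga2b by 0.85 ± 0.08, and P2rx1 fell. In 25 MHC class II and dendritic cell genes, 12 rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 change of 0.24 (adjusted p = 3.2e-08, and adjusted p = 0.077 with an estimated correlation). Ly6d changed by 0.86 ± 0.13, Cd83 by 0.77 ± 0.09 and H2-Ob by 0.67 ± 0.11, and Batf3 fell. Of 54 ribosomal protein genes, 24 rose and 0 fell (32 and 0 adjusted over the list alone), with a median log2 change of 0.26 (adjusted p = 1.6e-15, and adjusted p = 0.062 with an estimated correlation). Rps2 changed by 0.57 ± 0.11 and Rps7 by 0.50 ± 0.10.

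Smaller list rises followed. Of 12 genes in the primary granule list, 3 rose and 0 fell (5 and 1 adjusted over the list alone), with a median log2 change of 0.28 (adjusted p = 0.0085, and adjusted p = 0.31 with an estimated correlation). These were Ctsg (0.47 ± 0.11), the myeloperoxidase Mpo (0.42 ± 0.08) and Ms4a3 (0.38 ± 0.11), at low intensities of 253, 485 and 250.2 with HY209. Of 35 T and NK cell genes, 1 rose and 1 fell, with a median log2 change of 0.15 (adjusted p = 0.0015, and adjusted p = 0.36 with an estimated correlation). Ets1 changed by 0.59 ± 0.11 and the chemokine Ccl5 by -0.52 ± 0.09. Among 14 plasma cell genes, 2 rose and 0 fell, with a median log2 change of 0.10 (adjusted p = 0.018, and adjusted p = 0.27 with an estimated correlation). Mzb1 changed by 0.79 ± 0.11 and Irf4 by 0.63 ± 0.09. For 62 oxidative phosphorylation genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone), with a median log2 change of 0.11 (adjusted p = 0.0040, and adjusted p = 0.31 with an estimated correlation). Ndufa9 changed by 0.28 ± 0.08 (adjusted p = 0.049).

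With the preset correlation 8 lists fell with HY209, though most members of each did not pass the test, and none fell with an estimated correlation. Of 22 macrophage genes, 0 rose and 9 fell (0 and 12 adjusted over the list alone), with a median log2 change of -0.33 (adjusted p = 2.7e-07, and adjusted p = 0.073 with an estimated correlation). Beside Mrc1, the complement component C1qa changed by -0.70 ± 0.10 and Axl by -0.59 ± 0.08. Of 22 handling stress and immediate early genes, 1 rose and 8 fell (2 and 10 adjusted over the list alone), with a median log2 change of -0.23, or -0.22 at the bounds (adjusted p = 2.7e-07, and adjusted p = 0.062 with an estimated correlation). The member that rose was Hsph1 (0.84 ± 0.19). Among 47 inflammatory genes, 1 rose and 5 fell, with a median log2 change of -0.14 (adjusted p = 6.5e-05, and adjusted p = 0.062 with an estimated correlation). Ccl3 fell 1.51-fold from 9527 ± 563 to 6339 ± 697 (-0.60 ± 0.10), Junb changed by -0.48 ± 0.10, Ccl5, Ier3 and Csf1 also fell, and the costimulatory receptor gene Cd40 rose (0.69 ± 0.08). In 37 suppressor myeloid genes, 0 rose and 6 fell (1 and 9 adjusted over the list alone), with a median log2 change of -0.11 (adjusted p = 0.00028, and adjusted p = 0.062 with an estimated correlation). The growth factor Vegfa changed by -0.60 ± 0.09, the prostaglandin synthase Ptges by -0.51 ± 0.10 and Ido1, a tryptophan-degrading enzyme, by -0.49 ± 0.09. For 24 bile acid and cAMP genes, 0 rose and 5 fell (0 and 8 adjusted over the list alone), with a median log2 change of -0.15, or -0.11 at the bounds (adjusted p = 0.0040, and adjusted p = 0.062 with an estimated correlation). These were Fos, Fosb (at least 1.08-fold lower, below background on all 3 HY209 arrays), Vdr (-0.44 ± 0.12), the sterol transporter Abcg1 (-0.42 ± 0.09) and Rgs2. Of 55 interferon response genes, 0 rose and 2 fell (0 and 1 adjusted over the list alone), with a median log2 change of -0.09 (adjusted p = 0.0051, and adjusted p = 0.062 with an estimated correlation). Cxcl9 changed by -0.74 ± 0.08 and Rtp4 by -0.34 ± 0.10. Among 33 neutrophil maturity genes, 0 rose and 2 fell, with a median log2 change of -0.08 (adjusted p = 0.0058, and adjusted p = 0.077 with an estimated correlation). Wfdc21 changed by -0.40 ± 0.08 and Clec4e by -0.36 ± 0.09. Of 29 secondary and tertiary granule genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone), with a median log2 change of -0.10 (adjusted p = 0.026, and adjusted p = 0.082 with an estimated correlation). Orm1 changed by -0.31 ± 0.08.

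The remaining lists did not pass the list test. Monocyte genes had 1 higher and 0 lower of 19 (median 0.07, adjusted p = 0.081), with Irf4 higher. Eosinophil, basophil and mast cell genes had 1 higher and 2 lower of 15 (median -0.17, adjusted p = 0.17), with Gata2 higher and the ribonucleases Ear10 (-0.63 ± 0.10) and Ear6 (-0.58 ± 0.08) lower. Stem and progenitor genes had 3 higher and 0 lower of 19 (median -0.07, adjusted p = 0.86), with Egfl7 (1.28 ± 0.17), Gata2 and Tal1 higher and a mean of 0.07 against the negative median. Oxidative burst and antioxidant genes had 4 higher and 1 lower of 31 (median -0.04, adjusted p = 0.98), with Prdx2, Gpx3, Mgst3 and Hvcn1 higher and Txn1 lower. Unfolded protein response genes had 2 higher and 1 lower of 28, 3 and 1 adjusted over the list alone (median -0.03, adjusted p = 0.90), with Pdia4 (0.89 ± 0.15) and Psat1 higher, Ddit3 (-0.42 ± 0.08) lower and a mean of 0.03 against the negative median. Apoptosis regulators had 0 higher and 0 lower of 31 (median -0.03, adjusted p = 0.46). Glycolysis genes had 1 higher and 0 lower of 23, 0 and 0 adjusted over the list alone (median 0.04, adjusted p = 0.79), with Hk1 higher. Adhesion and migration receptors had 0 higher and 1 lower of 23, 0 and 0 adjusted over the list alone (median -0.12, adjusted p = 0.081), with Cxcr4 lower. Of the markers of suppressive granulocytes, Arg1 stood at 2038 ± 24.5 after LPS and 2561 ± 388 with HY209 (0.33 ± 0.11, adjusted p = 0.092). Il10 stood at 3354 ± 81.9 and 2927 ± 201 (-0.20 ± 0.08, adjusted p = 0.15), and Cd274 at 17595 ± 587 and 17028 ± 976 (-0.05 ± 0.08, adjusted p = 0.76). The log2 change was -0.07 ± 0.17 for Nos2, -0.02 ± 0.14 for Itgam, 0.07 ± 0.08 for Ly6c1, -0.02 ± 0.07 for S100a8 and -0.04 ± 0.10 for S100a9, none of them past the test. Gpbar1, which encodes the receptor of the bile salt, was below background in all 3 groups, at 140.5, 136 and 141, and was not tested. Ly6g had no annotated probe.

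**Figure D2:**
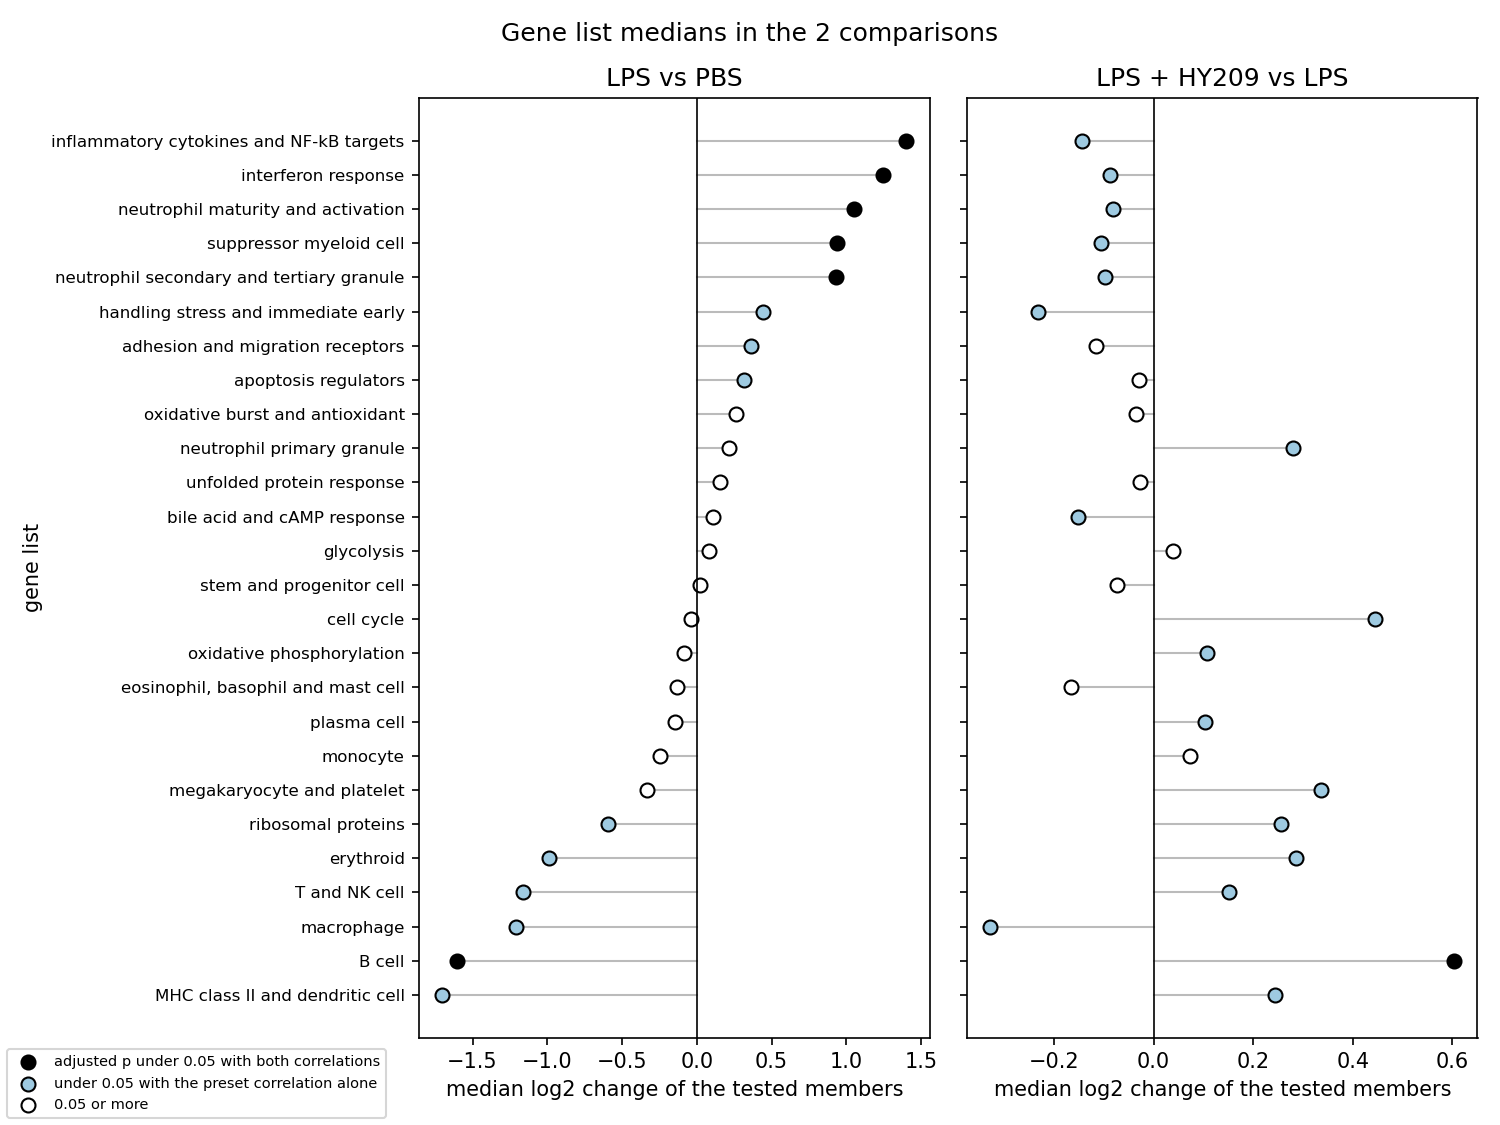
Median log2 change of the tested members of each of the 26 gene lists (y axis) for LPS against PBS (left) and LPS followed by HY209 against LPS (right), on x axes of different range. Black points passed the list test with both correlations, blue points with the preset correlation alone, and white points with neither. The B cell list had medians of -1.60 and 0.60.

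With limma, 627 genes were higher and 352 lower with HY209 at an adjusted p under 0.05, of which 19 and 5 changed at least 2-fold. The arrays of both groups did not overlap for 29.1% of the genes, against 10% by chance for 3 arrays against 3. The counts depended on single arrays, at 367 and 140 without LPS 1, 356 and 168 without LPS 3, and 252 and 138 without LPS_HY209 1. The secondary granule list lost its call without LPS 2 (adjusted p = 0.069), LPS_HY209 1 (adjusted p = 0.061) or LPS_HY209 3 (adjusted p = 0.058). The primary granule list lost it without LPS_HY209 1 (adjusted p = 0.070), as did the T and NK cell list (adjusted p = 0.061), and the plasma cell list without LPS_HY209 3 (adjusted p = 0.082). The adhesion list gained a call without LPS 1 (adjusted p = 0.025) or LPS 3 (adjusted p = 0.039). Among the genes named here, Ctsg, Ms4a3, Ndufa9, Orm1, Rtp4, Clec4e, Vdr, Fosb, Rgs2, Junb, Csf1, Rps7, Hsph1, Batf3, P2rx1, Gpx3, Mgst3, Hvcn1, Txn1, Psat1, Hk1 and Cxcr4 lost their call without at least 1 single array, with an adjusted p of up to 0.17.

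Most genes that HY209 changed had moved the other way after LPS. Of the 627 genes higher with HY209 than with LPS alone, 492 were lower in LPS than in PBS, where independent lists would share 188, and 22 were higher. Of the 352 lower genes, 255 were higher in LPS than in PBS, where independent lists would share 90.1, and 52 were lower. Egr1 rose with LPS (1.32 ± 0.09) and fell with HY209 back to a level near PBS (-0.03 ± 0.09 against PBS, adjusted p = 0.80), while Mrc1, Itgad and C6 fell in both steps. Both comparisons use the same LPS arrays, which sets their changes against each other without any effect. The covariance of the changes across genes was -0.0885, against -0.00556 simulated for unchanged groups, a difference of -0.0830. Pearson's r was -0.50, against -0.45 simulated. The simulation drew separate noise for each array. A deviation common to all 3 LPS arrays would enter both changes with opposite sign. It was not simulated, so the difference can hold it. Genes are not independent replicates. The 3 LPS arrays do not give 2 parts of 2 arrays each, so no split was made, and part of the overlap in called genes may come from the shared arrays.

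**Figure D3:**
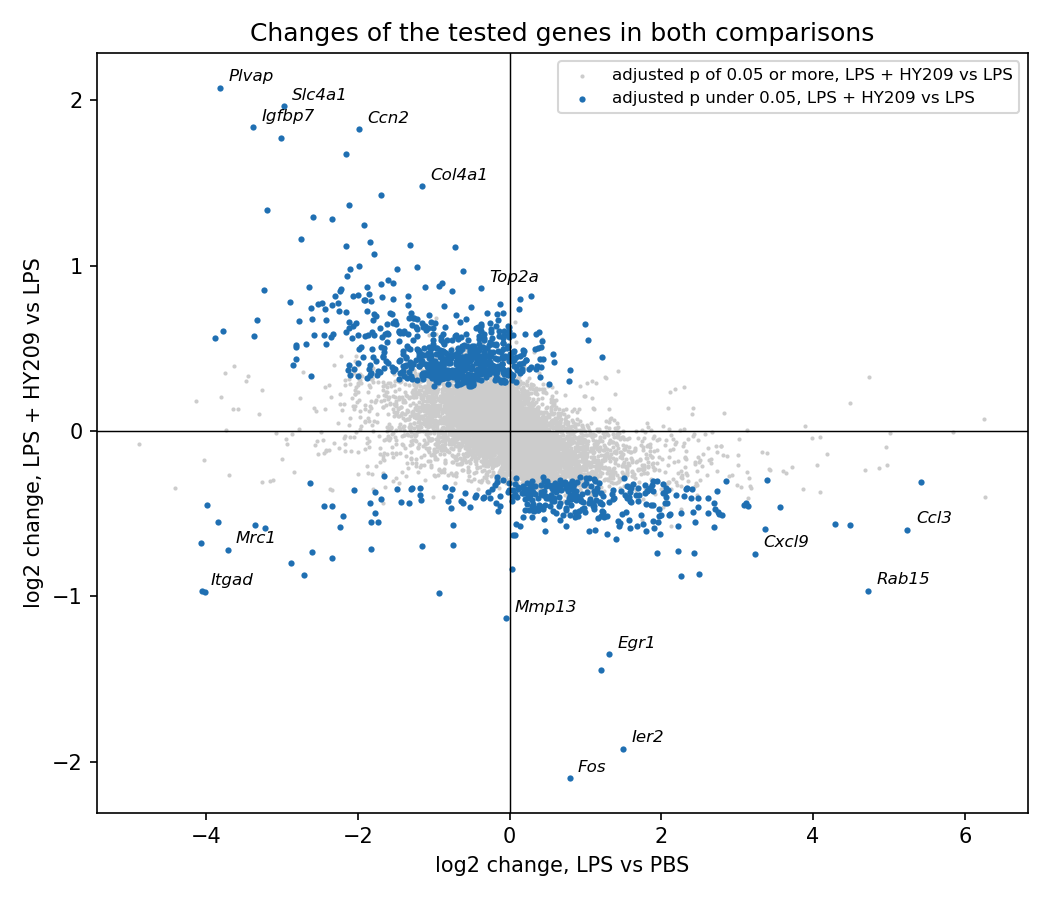
Log2 change of each of the 10273 tested genes for LPS against PBS (x axis) and for LPS followed by HY209 against LPS (y axis), with the 979 genes past the test in the second comparison in blue and some named genes labelled. Fos and Ier2 lie lowest at -2.10 and -1.92 on the y axis, and Plvap highest at 2.08.

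The final comparison, LPS followed by HY209 against PBS, shows how far the treated cells stood from those of mice given neither. Most inflammatory genes stayed above PBS. Saa3 rose 80.3-fold to 35173 ± 868 (log2 change 6.33 ± 0.13, adjusted p = 1.5e-11), Cxcl2 rose 58.6-fold to 8439.9 ± 2587 (5.87 ± 0.20) and Il10 27.3-fold to 2927 ± 201 (4.77 ± 0.09). Arg1 was at least 24.6-fold higher on the corrected scale, at an intensity of 2561 ± 388. Itgad fell 32.6-fold to 646 ± 47.8 (-5.03 ± 0.10, adjusted p = 1.3e-11), and Fos was below PBS (-1.31 ± 0.10).

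The other large rises were Prok2 (5.83 ± 0.19), Orm1 (5.11 ± 0.09), Gpr84 (5.01 ± 0.11), Upp1 (4.86 ± 0.08), Stfa2 (4.66 ± 0.13) and Ccl3 (4.65 ± 0.11). The other large falls were C6 (-4.98 ± 0.11), Hpgd (-4.96 ± 0.10), Trf (-4.75 ± 0.14), Slco2b1 (-4.75 ± 0.12), Mrc1 (-4.43 ± 0.10), Vstm4 (-4.43 ± 0.10), Igf1 (-4.39 ± 0.10), Rims3 (-3.97 ± 0.10) and Ccr3, which was at least 13.7-fold lower on the corrected scale. Itgam (2.41 ± 0.16), Cd274 (2.10 ± 0.09) and Ly6c1 (0.75 ± 0.09) rose. S100a8 (0.06 ± 0.08, adjusted p = 0.62) and S100a9 (0.18 ± 0.11, adjusted p = 0.22) did not pass the test. Nos2 changed by 0.65 ± 0.19 (adjusted p = 0.014) and lost its call without PBS 3 or LPS_HY209 1, with an adjusted p of up to 0.23.

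Of 55 interferon response genes, 49 rose and 1 fell (50 and 1 adjusted over the list alone), with a median log2 change of 1.13 (adjusted p = 6.2e-19, and adjusted p = 0.0023 with an estimated correlation). Isg15 changed by 2.66 ± 0.10, and Ifi27 fell. Of 47 inflammatory genes, 36 rose and 4 fell (37 and 4 adjusted over the list alone), with a median log2 change of 1.20, or 0.96 at the bounds (adjusted p = 1.1e-13, and adjusted p = 0.010 with an estimated correlation). Tnf changed by 3.50 ± 0.09, and Il18, Ccl9, Cd40 and Ccl5 fell. Of 37 suppressor myeloid genes, 24 rose and 5 fell, with a median log2 change of 0.69 (adjusted p = 1.9e-07, and adjusted p = 0.010 with an estimated correlation). Mrc1, Ccl6, Nt5e, Tgfb1 and Il10ra fell. Of 33 neutrophil maturity genes, 22 rose and 2 fell, with a median log2 change of 0.85 (adjusted p = 5.0e-09, and adjusted p = 0.011 with an estimated correlation). Il1r2 changed by 2.97 ± 0.10, and Ccl6 and Gadd45a fell. Of 29 secondary and tertiary granule genes, 18 rose and 4 fell, with a median log2 change of 0.60, or 0.47 at the bounds (adjusted p = 8.9e-06, and adjusted p = 0.014 with an estimated correlation). Lyz2, Fcnb, Camp and Ltf fell. Of 40 cell cycle genes, 26 rose and 1 fell, with a median log2 change of 0.42 (adjusted p = 1.5e-05, and adjusted p = 0.34 with an estimated correlation). Mcm10 changed by 1.16 ± 0.11, Uhrf1 by 0.93 ± 0.16, and Kif23 fell. Of 31 apoptosis regulators, 12 rose and 7 fell (14 and 7 adjusted over the list alone), with a median log2 change of 0.25, or 0.23 at the bounds (adjusted p = 0.023, and adjusted p = 0.12 with an estimated correlation). Fas changed by 1.83 ± 0.09.

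Lists for 5 cell types and for ribosomal proteins were below PBS with the preset correlation, and the B cell list alone also with an estimated one. For 35 T and NK cell genes, 0 rose and 31 fell, with a median log2 change of -1.01 (adjusted p = 1.8e-11, and adjusted p = 0.15 with an estimated correlation). Cd3g changed by -1.80 ± 0.12. For 25 B cell genes, 1 rose and 19 fell (1 and 20 adjusted over the list alone), with a median log2 change of -1.13 (adjusted p = 1.4e-07, and adjusted p = 0.010 with an estimated correlation). Fcmr changed by -2.11 ± 0.10, and Pou2f2 rose. For 22 macrophage genes, 2 rose and 16 fell (3 and 17 adjusted over the list alone), with a median log2 change of -1.58 (adjusted p = 1.4e-07, and adjusted p = 0.11 with an estimated correlation). Axl changed by -3.80 ± 0.09, and Marco and Ctsz rose. For 25 MHC class II and dendritic cell genes, 3 rose and 21 fell, with a median log2 change of -1.09 (adjusted p = 1.4e-07, and adjusted p = 0.13 with an estimated correlation). Ciita changed by -2.00 ± 0.12, and Irf7, Bst2 and Cd80 rose. For 33 erythroid genes, 4 rose and 20 fell (5 and 22 adjusted over the list alone), with a median log2 change of -0.51 (adjusted p = 0.0034, and adjusted p = 0.34 with an estimated correlation). Alas2 changed by -2.38 ± 0.17, and Isg20, Ube2l6, Nfe2 and Mt2 rose. For 54 ribosomal protein genes, 3 rose and 33 fell, with a median log2 change of -0.36 (adjusted p = 2.3e-05, and adjusted p = 0.17 with an estimated correlation). Rpl22 changed by -1.61 ± 0.11, and Rpl24, Rplp0 and Rpl7a rose.

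The other lists did not pass the list test. Primary granule genes had 6 higher and 3 lower of 12 (median 0.32, adjusted p = 0.31), with Igfbp4, Nkg7 and Ctsc lower. Monocyte genes had 5 higher and 9 lower of 19 (median -0.13, adjusted p = 0.55), with Cd14, Ms4a6d, Clec4a1, Ly6c1 and Lgals3 higher. Plasma cell genes had 1 higher and 4 lower of 14 (median -0.08, adjusted p = 0.60), with Edem1 higher and Mzb1, Tnfrsf17, Irf4 and Slamf7 lower. Megakaryocyte and platelet genes had 7 higher and 5 lower of 19 (median 0.09, adjusted p = 0.51), with Vwf, Clec1b, Ppbp, Alox12 and Gp5 lower. Eosinophil, basophil and mast cell genes had 4 higher and 4 lower of 15, 4 and 6 adjusted over the list alone (median -0.21, or -0.07 at the bounds, adjusted p = 0.80), with Ear6, Cd63, F2rl3 and Hdc higher and Ccr3, Prg3, Ear10 and Il4 lower. Stem and progenitor genes had 3 higher and 4 lower of 19 (median 0.09, adjusted p = 0.73), with Spi1, Etv6 and Gfi1b higher and Egfl7, Lmo2, Tal1 and Meis1 lower. Oxidative burst and antioxidant genes had 14 higher and 10 lower of 31, 15 and 10 adjusted over the list alone (median 0.25, adjusted p = 0.22). The bile acid and cAMP list had 7 higher and 7 lower of 24, 8 and 8 adjusted over the list alone (median 0.02, or 0.01 at the bounds, adjusted p = 0.73). Unfolded protein response genes had 10 higher and 10 lower of 28 (median 0.15, adjusted p = 0.70). Glycolysis genes had 7 higher and 4 lower of 23 (median 0.10, or 0.07 at the bounds, adjusted p = 0.27), with Hk2, Pdk1, Pfkm and Aldoc lower. Oxidative phosphorylation genes had 12 higher and 10 lower of 62, 11 and 9 adjusted over the list alone (median 0.01, adjusted p = 0.68). Adhesion and migration receptors had 10 higher and 7 lower of 23, 11 and 7 adjusted over the list alone (median 0.23, adjusted p = 0.079). Handling stress and immediate early genes had 7 higher and 8 lower of 22, 8 and 8 adjusted over the list alone (median -0.10, adjusted p = 0.89). For immediate early genes the mean was 0.05 against the negative median and test, and for unfolded protein response genes it was -0.02 against the positive median and test.

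With limma, 2209 genes were higher and 2664 lower than in PBS at an adjusted p under 0.05, of which 502 and 617 changed at least 2-fold, and array values did not overlap for 64.5% of the genes (20% by chance). Of the 13 lists called, 6 kept their call with an estimated correlation. The apoptosis list lost its call with a stricter filter on dim probes (adjusted p = 0.052), and the adhesion list gained one without LPS_HY209 3 (adjusted p = 0.047), with no filter on dim probes (adjusted p = 0.042) and with every probe tested (adjusted p = 0.029). Of the genes higher in LPS than in PBS, 1965 were also higher here, where independent lists would share 565, and 2 were lower. Of the genes lower after LPS, 2473 were also lower here, where independent lists would share 799, and 6 were higher. Across the 10273 genes the covariance of both changes was 0.534, against 0.00833 simulated for unchanged groups that share the PBS arrays, a difference of 0.526, and Pearson's r was 0.96, against 0.60 simulated. Here, too, no split into 2 parts of 2 arrays can be made, and part of the overlap in called genes may come from the shared PBS arrays. A deviation common to the PBS arrays was not simulated either. Among the genes named here, Gadd45a, Camp, Fcnb, Ltf, Ccl5, Il10ra, Ctsz, Rpl7a, Alox12, Gp5, Aldoc, Edem1 and Slamf7 lost their call without at least 1 single array, with an adjusted p of up to 0.26.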

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

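The background offset of 16 and the centring were added after the data were seen. The named genes had 9179 values over 20 alternative settings. Of these, 8910 kept their side of the threshold, 265 lost the call (157 of them in LPS_HY209 vs LPS), 4 gained one and 0 reversed. A reversal was counted only where the main or the alternative value passed the test. Changes of direction in genes without a call are among the 8910. Leaving out each array in turn ended the call of 18 of 180 named genes in LPS vs PBS, 26 of 95 in LPS_HY209 vs LPS and 17 of 159 in LPS_HY209 vs PBS. In LPS_HY209 vs LPS it gave 252 to 748 genes higher and 138 to 376 lower, with fewer arrays in the fit (1 PBS array alone is assumed to vary like the other groups). The lower count was 232 with no filter on dim probes, where more genes are tested. With an estimated correlation, 6, 1 and 6 lists were called in LPS vs PBS, LPS_HY209 vs LPS and LPS_HY209 vs PBS. The other counts of genes and lists stayed within 1.5 times the main value in every setting. The covariance of the changes LPS vs PBS and LPS_HY209 vs PBS was 0.412 with no background correction, 0.428 with the submitters' values, 0.336 with no filter, 0.641 with the stricter filter, 0.526 with the replicate block, 0.638 with the offset of 16 and 0.524 to 0.547 leaving out each array, and the cause was not tested. The replicate block gave 756 genes higher and 450 lower in LPS_HY209 vs LPS. Blocks for slides were not run because no slide is named. The percentile scaling ran on values already quantile normalized. Signal over background limits the dim genes: Gpbar1 could not be tested.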

Other observations

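The lists for endothelial and stromal cells, the test on the share of the main cell type, both tests on the share of granulocytes and the tests on endothelial cells and on a single array were chosen after the results were seen. Of 42 tested endothelial genes, 6 rose and 29 fell in LPS vs PBS (6 and 30 adjusted over the list alone), with a median of -1.03, or -0.92 at the bounds (adjusted p = 6.0e-06, and adjusted p = 0.36 with an estimated correlation). With HY209 against LPS, 21 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 0.33, or 0.24 at the bounds (adjusted p = 8.4e-14, and adjusted p = 0.11 with an estimated correlation). Against PBS, 8 rose and 23 fell (8 and 25 adjusted over the list alone), with a median of -0.50 (adjusted p = 0.010, and adjusted p = 0.66 with an estimated correlation). In the mean level of a list, LPS_HY209 2 lay nearest to LPS, at -0.12 for endothelial genes (0.22 and 0.13 in the other HY209 arrays, -0.49 to -0.46 in LPS) and -0.08 for erythroid genes (0.14 and 0.10, -0.39 to -0.36 in LPS). For T and NK cell genes its level of -0.35 lay within the LPS range of -0.38 to -0.32. The same held for oxidative phosphorylation genes, at -0.022 within -0.090 to -0.003. The 10 endothelial members seen in the first tables led the list and are part of these counts, which therefore partly restate what was first seen. The other 32 members had a median of 0.196 with HY209 against LPS (0.13 at the bounds). Egfl7 and Slco2a1 changed by 1.28 ± 0.17 and 1.14 ± 0.12 with HY209. Stromal genes (18 tested) had 3 higher and 2 lower with HY209 (5 and 2 adjusted over the list alone; median 0.01, adjusted p = 0.33) and 5 higher and 6 lower after LPS (median 0.05, or 0.02 at the bounds, adjusted p = 0.87). Against PBS they had 6 higher and 5 lower with HY209 (median -0.01, adjusted p = 0.81).

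Some genes past the test between HY209 and LPS did not pass it between LPS and PBS, 113 of the 627 higher and 45 of the 352 lower, and whether the steps differ for them was not tested. The largest rises among them were Pclaf (0.82 ± 0.13), a factor of DNA replication, Uhrf1 (0.80 ± 0.14), the platelet receptor chain Gp1bb (0.77 ± 0.10), Cdca3 (0.73 ± 0.13) and the platelet chemokine Pf4 (0.71 ± 0.10). The largest falls were Mmp13 (-1.13 ± 0.11), the nuclease Dnase1l3 (-0.84 ± 0.11, from 3088 ± 89.8 to 1774 ± 269), Ear10 (-0.63 ± 0.10) and the ubiquitin-like Ubd (-0.63 ± 0.09). Among the 10 ways to split the 6 arrays of both groups into 3 and 3, the real one called 979 genes and the highest other called 4, and 1 split gave as many. With 10 splits no share under 0.05 can be had.

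Many endothelial and erythroid genes were higher in LPS_HY209 than in LPS. A lower share of the main cell type would raise markers of all other types. The B, T and NK, plasma, megakaryocyte, erythroid and endothelial lists had medians from 0.10 to 0.60. Further lists of other cell types, which this test left out, did not all rise. Their medians were 0.24 (MHC class II and dendritic cell), 0.01 (stromal), -0.07 (stem and progenitor) and -0.17 (eosinophil, basophil and mast cell). Of these, the MHC class II and dendritic cell list alone passed the list test, with the preset correlation. The macrophage list had a median of -0.328, with 0 of 22 higher and 9 lower (0 and 12 adjusted over the list alone; adjusted p = 2.7e-07, and adjusted p = 0.073 with an estimated correlation). A lower share alone would not give that fall, but a lower share beside a separate fall of macrophage genes stays open. A single aberrant array is argued against by 3 HY209 arrays above every LPS array in the median of the endothelial genes not first seen (0.08, -0.12 and 0.06 against at most -0.22), though LPS_HY209 2 lay lowest. More endothelial cells in the fractions stay a candidate explanation, since those genes had a median log2 change of 0.196 (0.13 at the bounds; 11 of 32 rose and 0 fell, 12 and 0 adjusted over the list alone, adjusted p = 6.9e-06, and adjusted p = 0.11 with an estimated correlation). The Gr1 sort is meant to leave such cells out, but it did not remove all endothelial transcripts. In PBS, Igfbp7 stood at 6227 and Stab2 at 3525, far above the threshold of 168, and others such as Kdr at 163 did not exceed it. Of the 42 members, 3 stand in other lists. Plvap (292 to 1086) and Igfbp7 (660.0 to 2282) moved far, while the abundant Stab2 (356 to 391, 3525 in PBS) and Ece1 (479 to 439) did not pass the test, so such cells would need to be poor in both, and an effect of HY209 on the spleen stays open.

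Fos, Ier2 and Egr1, which respond to handling and sorting as well as to signals, were lower in LPS_HY209 than in LPS. The test on the rest of their list was set after these falls had been seen. A weaker handling response would lower the rest of that list too, and its other 19 members had a median of -0.220 (-0.15 at the bounds), with 1 higher and 5 lower (2 and 7 adjusted over the list alone; adjusted p = 0.00055, and adjusted p = 0.11 with an estimated correlation). That is consistent with a handling difference, and equally with an effect of HY209 on immediate early genes, which this test does not separate. The labels give no sorting times. Fos ended below PBS (-1.31 ± 0.10), while Egr1 did not differ past the test from PBS (-0.03 ± 0.09).

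Several lists of other cell types were lower in LPS than in PBS. Whether a higher share of granulocytes in the sorted fractions gives this cannot be told apart from a change in gene activity or in cell numbers of the spleen, since 9 of 11 lists had a median below 0 and none was called higher, but stromal genes (0.0501) and stem and progenitor genes (0.02) had medians above 0. As the only cause it would lower all other types alike, and over 154 members well above background in the mean of both groups the medians spread by 2.63, from -1.95 for MHC class II and dendritic cell genes to 0.68 for eosinophil, basophil and mast cell genes (permutation p = 0.031 over the genes, which are not independent). Without the eosinophil and stem cell lists, which may hold genes that granulocytes express, the spread was 1.90 (permutation p = 0.093). Over all members, dim ones included, the permutation p was 0.0016 with these 2 lists and 0.0012 without them. Over members well above background in PBS it was 0.03 and 0.055. The outcome depended on the members and lists kept, so this explanation stays open as well. The labels give more than 95% CD11b+ cells without a value per sample. On the PBS arrays the neutrophil gene S100a8 stood at 58814, but Itgam, which encodes CD11b, at 535. Genes from lists of other cell types stood high there, such as Axl at 46528 and Mrc1 at 19088 (macrophage) and Ets1 at 21128 (T and NK cell). The make-up of the PBS fractions is therefore not settled, and LPS against PBS may compare unlike mixtures of cells.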
